A study of Caenorhabditis elegans with 4 samples.

How the data were processed

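RNA was taken from whole Bristol N2 hermaphrodites kept for 5 days on OP50 or ETEC bacteria, with 2 libraries per group. Per the labels' protocols, total RNA was purified with a column kit, polyadenylated RNA was selected on beads, and libraries were made with a stranded random-primed kit. The deposited files hold raw read counts per gene, 1 library per file, beside the exon coordinates, strand, summed exon length and Gene Ontology terms of each gene. Per the submitters' processing notes, the tools were Trim Galore 0.6.5, Trimmomatic 0.39, cutadapt 2.7, STAR 2.7.2b and featureCounts 1.6.4, and the genome ce11, the same assembly as WBcel235. The counts were not normalized, since they are whole numbers with a different total in each library. The strand setting and the treatment of reads that match several genes or overlapping genes are not given in the sources used here. Reads counted without strand would add antisense partners together, and discarded multi-mapping reads would lower the counts of near-identical paralogs.

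Groups and replicate numbers were taken from the sample titles. The deposited files number the second library of each group 3 where its title numbers it 2, and what the 3 stands for is not given in the sources used here, so the numbers may not count all replicates made. The files list 46904 genes. Of the identifiers, 46817 occur in the reference annotation used here for gene biotypes, and 69.1% of those have the same chromosome, start and end there, so coordinates are printed as the files give them. Totals ran from 23318172 to 25870039 counts per library. Replicates of a group differed by more than sampling noise (chi-square over degrees of freedom of 175 for OP50 and 460 for ETEC, over genes with at least 10 counts), so none was treated as a duplicate.

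The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with TMM normalization, the default filter on low counts, robust dispersion, group as the only term and Benjamini-Hochberg adjustment at 0.05. It tested 14594 genes. Levels are TMM-scaled CPM, read counts scaled to library size, and log2 changes are ETEC minus OP50. The standard error of a log2 change was taken as its size over the root of the F statistic. For genes with 1 to 3 counts over both OP50 libraries a ratio is given with its exact 95% interval, from the binomial distribution of the group counts, and for a gene with 0 counts a lower bound against a floor of 3 counts over the group. Such intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

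Before the data were examined, 40 gene lists were fixed, 31 of responses and 9 of cell types or stages, by gene symbol or name pattern, and 5 named members had no match. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, beside an estimated correlation and the rotation test fry. With an estimated correlation no list was called (lowest adjusted p 0.905), nor with fry (lowest adjusted p 0.553). In these fits limma gave every gene the same variance. The shift of a list is the mean log2 change of its members minus that of the other tested genes. The shift in 1 library is the same difference for that library's log2 CPM minus the mean of the OP50 libraries, so the values of the 2 OP50 libraries mirror each other and the libraries lie 2 times that value apart.

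The rule for named genes was also fixed beforehand. It took the 8 largest rises and 8 largest falls among called genes with at least 10 CPM in the higher group and separated libraries (8 and 1 genes met it). It then took, per list with called members, the member with the smallest p in each direction and the next one in the direction with more calls, and 11 readout genes whatever their result. The 16 genes called also without ETEC replicate 2, and ugt-63, were added after their values were seen, as were genes named in the closing section.

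Alternatives fixed beforehand were DESeq2 1.42.0 size factors, upper-quartile factors, no filter on low counts, a filter of 5 CPM in 2 libraries, the DESeq2 Wald test, limma-voom, leaving out the 20 most abundant genes, the replicate number as a block, leaving out each library, the other list tests and leaving out germline, sperm and embryo genes. The length correction was chosen after seeing the data. It takes from each library a lowess trend (span 0.3) of log2 CPM on log2 exon length, fitted over genes with a mean log2 CPM above 2, relative to the mean of the libraries. A crossed replicate block was added as well. Where a group keeps 1 library, that library is assumed to vary like the other group.

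The fits were tested on simulated counts with the means and library sizes of these libraries. For ETEC against OP50, over 14278 simulated genes, true log2 changes of 2, 3 and 4 were called in 15%, 51.4% and 87.7% of changed genes, with 3 false calls among 105. With a length trend put into 1 library, over 14312 genes, the shares were 10.7%, 36.1% and 84.4% without the correction, with 7 false calls among 93, and 16.1%, 61.1% and 96.9% with it, with 6 false calls among 121. A list shifted on purpose was called among 30 lists of random genes, and 0 of the others were. In that run the genes varied independently and no library had a length trend. It therefore cannot show how often lists of genes that vary together are called falsely. In the gene runs too, genes varied independently, at a dispersion taken from the real counts with the trend of ETEC replicate 2 in them. No simulated library departed from the others as a whole, apart from the added length trend. The false calls given therefore do not cover such a departure.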

Results

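Gene expression was measured by RNA sequencing in whole hermaphrodites of the wild-type Caenorhabditis elegans strain Bristol N2 that had been fed either of 2 bacteria. OP50 is the Escherichia coli strain on which the worm is ordinarily grown in the laboratory, and ETEC is enterotoxigenic Escherichia coli, a diarrhoeal pathogen that makes enterotoxins. Worms 3 days old were kept for 5 days on one or the other bacterium and collected at day 8, about 200 worms per collection. There were 2 libraries per group. The libraries held 23878805 and 25870039 counts for OP50 replicates 1 and 2, and 23318172 and 23907896 counts for ETEC replicates 1 and 2. Between 18536 and 19676 genes had at least 1 count. Nothing in the labels says that the replicates came from separate cultures, so the p-values of genes below measure the spread between these libraries, which may be technical. The p-values of lists with the preset correlation compare members with the other genes. They rest on the spread across genes and do not measure the spread between libraries. The only comparison of the design is ETEC against OP50, which asks which transcripts of the worm differ when the pathogen replaces the standard food.

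With all 4 libraries in the test, a set of genes close to silent on OP50 had higher transcript levels on ETEC, and few genes were called lower. Of 14594 genes tested, 56 differed between the groups, 50 higher and 6 lower on ETEC (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). In 48 of the 50 the level was higher in ETEC replicate 2, which stood apart from the other libraries, than in ETEC replicate 1. The balance of higher and lower calls may therefore rest on that library. The 50 raised genes had a median of 0.289 CPM (counts scaled to library size) on OP50 and 5.81 CPM on ETEC. Their log2 changes had a median of 3.97, also with the 1 gene without any OP50 count set at its lower bound, and none was under 2.89. They included cuticle collagens, insulin-like peptides, pals genes of the intracellular pathogen response and pqn genes, which encode proteins with prion-like glutamine- and asparagine-rich domains. In 55 of the 56 genes both ETEC libraries lay on one side of both OP50 libraries, which selection by a group test on these same libraries favours. Over all tested genes this held for 22.2%, below the 33.3% that chance gives for 2 against 2, both directions together.

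The largest rise among called genes with a group mean of at least 10 CPM was that of F56A6.5 (WBGene00044427, chromosome I, 582288 to 583748, minus strand, coordinates of WBcel235 as the files list them). It went from 0.144 and 0.142 CPM on OP50 to 8.74 and 13.5 CPM on ETEC, a log2 change of 6.23 (SE 0.93, adjusted p = 1.85e-07). C08E3.1 (chromosome II, 1633806 to 1634089) rose by a log2 of 4.81 (SE 0.83, adjusted p = 2.85e-05), from 0.957 and 0.462 CPM to 5.45 and 34.2 CPM. T22F3.11 (chromosome V, 3612173 to 3614551) rose by 4.68 (SE 0.83, adjusted p = 3.36e-05) and F40H7.12 (chromosome II, 3687791 to 3688691) by 3.71 (SE 0.78, adjusted p = 0.00161). The other 4 genes of this kind were Y46H3A.5, the homeobox gene ceh-5, the collagen gene col-7 and pqn-60, with log2 changes between 3.04 and 3.26. Without ETEC replicate 2 these 4 had log2 changes of 2.60, 1.88, 2.27 and 1.57 and none was called (adjusted p = 0.0565, 1, 0.348 and 1), and that of C08E3.1 was 2.96 (adjusted p = 0.0355). The only fall at this level was that of the cuticle collagen gene col-183 (WBGene00000756, chromosome X, 13466737 to 13467736, minus strand), from 60.5 and 19.7 CPM to 1.71 and 4.28 CPM (log2 change -3.74, SE 0.82, adjusted p = 0.00306).

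The number of calls depended on which libraries were kept. Without ETEC replicate 2, 21 genes were called, of which 16 were among the 56. Without ETEC replicate 1 there were 2112 calls, all 56 among them. With 1 OP50 library left out, 2 genes were called without replicate 1 and 0 without replicate 2, where 213 had an unadjusted p under 0.05 by edgeR, DESeq2 called 1 gene (292 at that p) and limma-voom 0 (106). Of the 18 called genes that the rule for named genes took, none kept its call without OP50 replicate 1 or without OP50 replicate 2, and 9 of the 17 tested kept it without ETEC replicate 2. The log2 changes of these 18 genes kept their sign without either OP50 library. Without OP50 replicates 1 and 2 that of F56A6.5 was 6.20 and 6.27, that of ins-8 5.85 and 5.55, and that of col-183 -2.76 and -4.28. Those fits keep 1 OP50 library, so a call lost there does not show that the change rests on the library left out. Likewise, the fits that leave out an ETEC library take the spread of each gene from the OP50 pair alone. A call made or kept in them does not take in the spread between the ETEC libraries. In 48 of the 50 raised genes ETEC replicate 2 had the higher level of the ETEC pair. The 16 genes called with and without ETEC replicate 2, picked out after their values were seen, were also called once a trend with exon length was taken out of the counts. The 13 raised ones were F56A6.5, hmg-6, C08E3.1, F40H7.12, bli-2, C27H5.6, bli-1, Y71H2AR.2, ins-8, trx-5, T22F3.11, F11A5.3 and F09C6.13, and the 3 lowered ones oac-32, spp-12 and col-183. Of these, oac-32, named for its resemblance to O-acyltransferases, went from 11.7 and 5.05 CPM to 0.250 and 0.411 CPM (log2 change -4.64, SE 0.85, adjusted p = 8.3e-05).

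**Figure D1:**
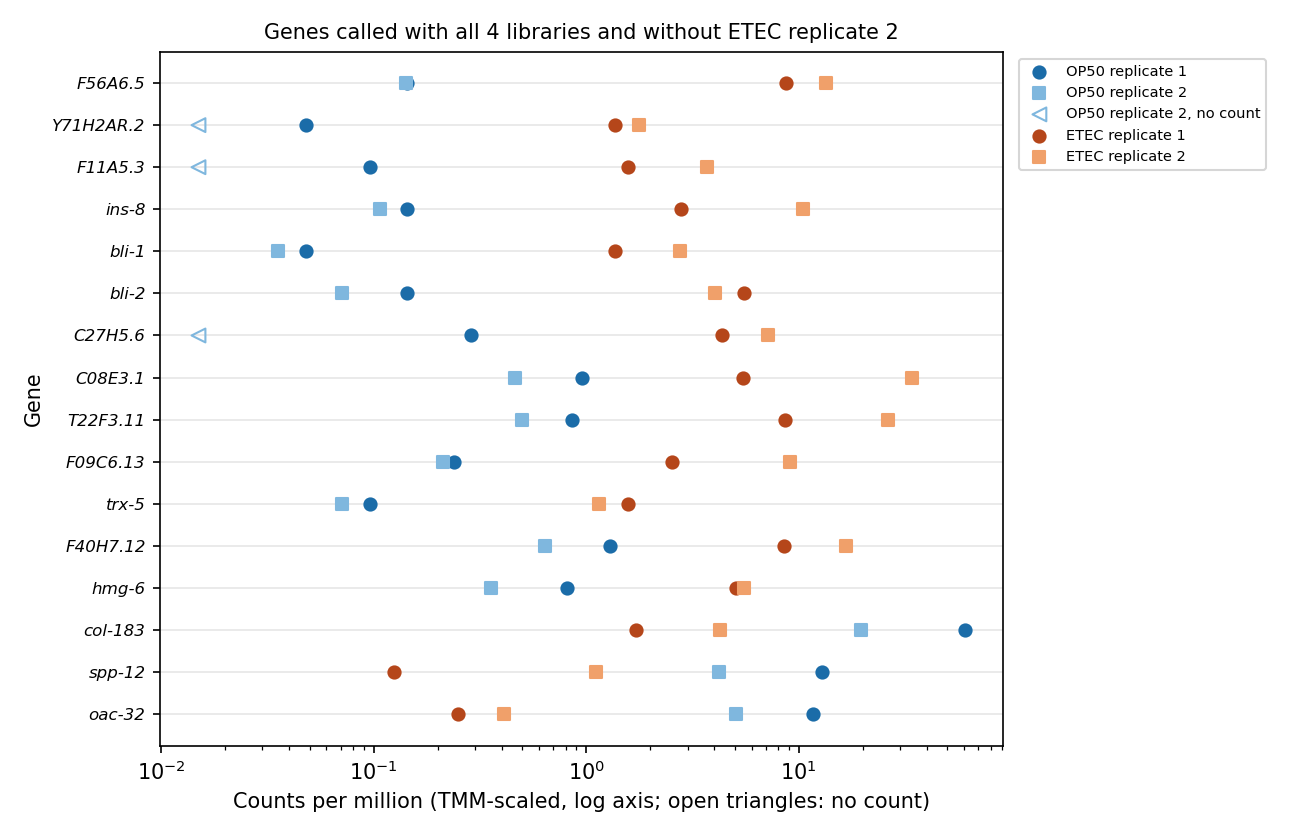
Level of the 16 genes called both with all 4 libraries and without ETEC replicate 2, in TMM-scaled CPM on a log axis, 1 point per library (blue OP50, orange ETEC, circles replicate 1, squares replicate 2, open triangles no count). F56A6.5 is at 0.144 and 0.142 CPM in the OP50 libraries and at 8.74 and 13.5 CPM in the ETEC libraries, and for oac-32, spp-12 and col-183 the OP50 points lie to the right of the ETEC points.

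The intracellular pathogen response, which microsporidia and the Orsay virus are known to induce, rose as a list. The list took all pals genes by name, whether or not each is known to be induced, with ubiquitin ligase genes and some others. Its 38 tested members lay 1.14 log2 units above the other genes (camera, adjusted p = 1.15e-14 over 40 lists; adjusted p = 0.905 with an estimated correlation). Of them, 36 had a positive change, 3 were called higher over all genes tested and none lower, and 10 were higher when adjusted over the list alone. The reporter gene of the response, pals-5 (WBGene00007659, chromosome I, 13130808 to 13132464), went from 0.718 and 0.711 CPM to 3 and 12.9 CPM (log2 change 3.46, SE 0.79, adjusted p = 0.00611). The gene pals-10 (chromosome I, 13107140 to 13107457) had 1 count on OP50 and 55 on ETEC, a ratio of 55.8 with a 95% counting interval of 9.6 to 2240 (edgeR adjusted p = 0.00618). Neither pals gene was called without ETEC replicate 2 (adjusted p = 0.836 and 0.398), where the log2 change of pals-5 was 2.06. The shift of the list was 0.63 in ETEC replicate 1 and 1.65 in ETEC replicate 2 against the OP50 mean, where the OP50 libraries stood at -0.19 and 0.19. Without ETEC replicate 2 it was 0.63 (adjusted p = 5.63e-08).

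The insulin-like peptides, secreted ligands of the insulin receptor DAF-2, rose by 1.37 log2 units relative to the other genes (24 tested members, adjusted p = 1.12e-14; adjusted p = 0.905 with an estimated correlation). Members called higher numbered 4, and 10 were higher adjusted over the list alone, with none lower. The gene ins-8 (WBGene00002091, chromosome IV, 9680387 to 9680941) went from 0.144 and 0.107 CPM to 2.79 and 10.5 CPM (log2 change 5.70, SE 0.95, adjusted p = 8.7e-06), and ins-19 (chromosome II, 3126037 to 3126441) from 0.191 and 0.356 CPM to 1.41 and 8.02 CPM (log2 change 4.06, SE 0.87, adjusted p = 0.00188). Without ETEC replicate 2, ins-8 kept its call (log2 change 4.44, adjusted p = 0.00135) and ins-19 did not (log2 change 2.32, adjusted p = 1). The members have short exons, a median of 503 nt. The list shift was 0.67 with the length trend taken out and 0.44 without ETEC replicate 2, both still called (adjusted p = 5.02e-05 and 0.00204), and 0.84 without OP50 replicate 2 (adjusted p = 1.34e-05). With no filter on low counts it was 0.87 (adjusted p = 8.06e-09).

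Collagen genes, most of which encode cuticle components, rose by 0.88 log2 units as a list of 153 tested members (adjusted p = 1.36e-18; adjusted p = 0.905 with an estimated correlation). A positive change was found in 134 of them. Over all genes 4 were called higher and 1, col-183, lower, and adjusted over the list alone 14 were higher and 1 lower. The gene bli-2 (chromosome II, 5651394 to 5652449), a collagen needed for an unblistered adult cuticle, went from 0.144 and 0.0711 CPM to 5.53 and 4.03 CPM (log2 change 5.46, SE 0.97, adjusted p = 3.36e-05). Its partner bli-1 (chromosome II, 10708765 to 10712156) had 2 counts on OP50 and 100 on ETEC, a ratio of 50.7 with a 95% counting interval of 13.7 to 424 (edgeR adjusted p = 0.00078). The shift of the list was 0.22 in ETEC replicate 1 and 1.53 in ETEC replicate 2, with the OP50 libraries at 0.33 and -0.33. It was 0.23 without ETEC replicate 2 (adjusted p = 0.00828), 0.50 without OP50 replicate 2 (adjusted p = 1.37e-05) and 1.44 without ETEC replicate 1 (adjusted p = 9.86e-16). Of the hypodermis markers, 14 tested genes that hold bli-1 as the only called member, 6 had a positive change, and the median log2 change was 0.01. Their list shift was 0.34 (camera adjusted p = 0.194, with 1 member higher adjusted over the list alone). With the length trend taken out it was 0.49 (adjusted p = 0.0366; adjusted p = 0.908 with an estimated correlation).

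The pharynx markers, taken mostly by the gene names pqn, abu and phat, rose by 0.29 as a list (77 tested members, camera adjusted p = 0.0273, and 0.905 with an estimated correlation). A positive change was found in 48 of them, and the median log2 change was 0.15. The name pqn stands for the protein domains given above and not for a tissue, so the list marks the pharynx only loosely. There were 3 members called higher, the same number adjusted over the list alone, and none lower. The neighbouring genes pqn-98 (chromosome V, 603665 to 604205) and pqn-97 (chromosome V, 609144 to 609726) were among them. No read of pqn-98 was counted on OP50 against 95 on ETEC, at least 32.1-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 3.36e-05). The level of pqn-97 went from 0.0957 and 0.107 CPM to 0.582 and 5.23 CPM (log2 change 4.77, SE 0.98, adjusted p = 0.000952, and 2.46 with adjusted p = 1 without ETEC replicate 2). The pharynx list lost its call without OP50 replicate 1 (shift 0.04, adjusted p = 0.888) and without ETEC replicate 1 (shift 0.23, adjusted p = 0.401) and had a shift of 0.46 without OP50 replicate 2 (adjusted p = 0.00151). The call was also lost with no filter on low counts (shift 0.21, adjusted p = 0.109) and with a filter of 5 CPM (shift 0.24, adjusted p = 0.0751), and pqn-98 was not tested without ETEC replicate 2.

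UDP-glucuronosyltransferases, enzymes that conjugate small molecules in detoxification, fell as a list by 0.52 log2 units (55 tested members, adjusted p = 0.000187; adjusted p = 0.905 with an estimated correlation). No single member was called over all genes, and 5 were lower adjusted over the list alone. In 22 members both ETEC libraries lay below both OP50 libraries and in 5 above, where chance gives 33.3% for both directions together. The member with the smallest p, ugt-63, stood at 8.57 and 7.54 CPM on OP50 and 1.21 and 1.40 CPM on ETEC (log2 change -2.62, SE 0.76, adjusted p = 0.0899). This fall was larger in ETEC replicate 1 (list shift -0.72) than in ETEC replicate 2 (-0.31), and with the length trend taken out the shifts were -0.74 and 0.22. The corrected list shift was -0.26 (adjusted p = 0.049; adjusted p = 0.908 with an estimated correlation). Without ETEC replicate 1 the list was not called (shift -0.40, adjusted p = 0.161). Cytochromes P450, the oxidases of the same detoxification route, had a list shift of -0.30 (56 tested members, adjusted p = 0.0388; adjusted p = 0.905 with an estimated correlation), with no member called. That call was lost with the length trend taken out (shift -0.09, adjusted p = 0.547), with a filter of 5 CPM (shift -0.04, adjusted p = 0.845), without ETEC replicate 1 (shift -0.38, adjusted p = 0.164) and without OP50 replicate 2 (shift -0.15, adjusted p = 0.372), and the shift was -0.48 without OP50 replicate 1 (adjusted p = 0.00437).

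The remaining 13 called lists were called only with ETEC replicate 2 among the libraries, apart from a call in the opposite direction for antimicrobial peptides and the mitochondrial genome (shift -0.57, adjusted p = 0.00204) without it. Sperm markers had a shift of 1 (47 tested members, camera adjusted p = 2.54e-13, and 0.905 with an estimated correlation), of 0.20 in ETEC replicate 1 and 1.80 in ETEC replicate 2. Oocyte and germline markers had one of -0.70 (43 tested members, camera adjusted p = 1.61e-06, and 0.905 with an estimated correlation), of -0.07 and -1.34. With the length trend taken out, the sperm shift was 0.34 (camera adjusted p = 0.0101), with 0.30 and 0.38 in the ETEC libraries and 0.22 and -0.22 in the OP50 libraries. That of the oocyte and germline markers was then -0.49 (camera adjusted p = 0.000234), with -0.11 and -0.87 in the ETEC libraries. With an estimated correlation both of these corrected shifts had an adjusted p of 0.908. Adjusted over the list alone, 5 sperm markers were higher, and of the antimicrobial peptides 1 was higher and 2 were lower; the other lists of the 13 had none. Shifts above 0 were also called for histones (0.65), the mitochondrial genome (0.51), FMRFamide-like neuropeptides (0.50), antimicrobial peptides (0.37) and cytosolic ribosomal proteins (0.27). Shifts below 0 were called for vitellogenins (-1.02), the yolk proteins, and for DNA replication and cell cycle genes (-0.55), the unfolded protein response of the endoplasmic reticulum (-0.54), fatty acid synthesis (-0.45), propionate and methionine metabolism (-0.44) and the proteasome (-0.38). Without ETEC replicate 2 the shifts were 0.18 (sperm), -0.07 (oocyte and germline), 0.08 (histones), 0.07 (neuropeptides), -0.16 (ribosomal proteins), -0.04 (vitellogenins), 0.16 (DNA replication), 0.16 (endoplasmic reticulum), -0.24 (fatty acid synthesis), -0.19 (propionate and methionine) and -0.01 (proteasome), none of them called. Calls were also lost without OP50 replicate 2 for histones (0.14), the mitochondrial genome (0.05), neuropeptides (0.06), antimicrobial peptides (0.24), ribosomal proteins (-0.20) and DNA replication (-0.38). The same held without OP50 replicate 1 for vitellogenins (-0.90), fatty acid synthesis (-0.32), propionate and methionine (-0.37) and the proteasome (-0.29), and without ETEC replicate 1 for propionate and methionine (-0.76). With a filter of 5 CPM the endoplasmic reticulum response (-0.36), fatty acid synthesis (-0.31), propionate and methionine (-0.35) and the proteasome (-0.21) were not called, and with no filter the mitochondrial genome (0.38) and ribosomal proteins (0.18) were not. The adjusted p with an estimated correlation was between 0.905 and 0.973 for each. Among their members only the saposin-like antimicrobial gene spp-12 (WBGene00004997, chromosome V, 13889918 to 13890295) was called, at 8.49 ± 6.07 CPM (SD, n = 2) on OP50 and 0.618 ± 0.697 CPM (SD, n = 2) on ETEC (log2 change -3.76, SE 0.81, adjusted p = 0.00188, and -6.03 without ETEC replicate 2). The antimicrobial peptide list itself turned to -0.37 (adjusted p = 0.00292) with the length trend taken out and to -0.48 (adjusted p = 1.54e-06) without ETEC replicate 2.

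**Figure D2:**
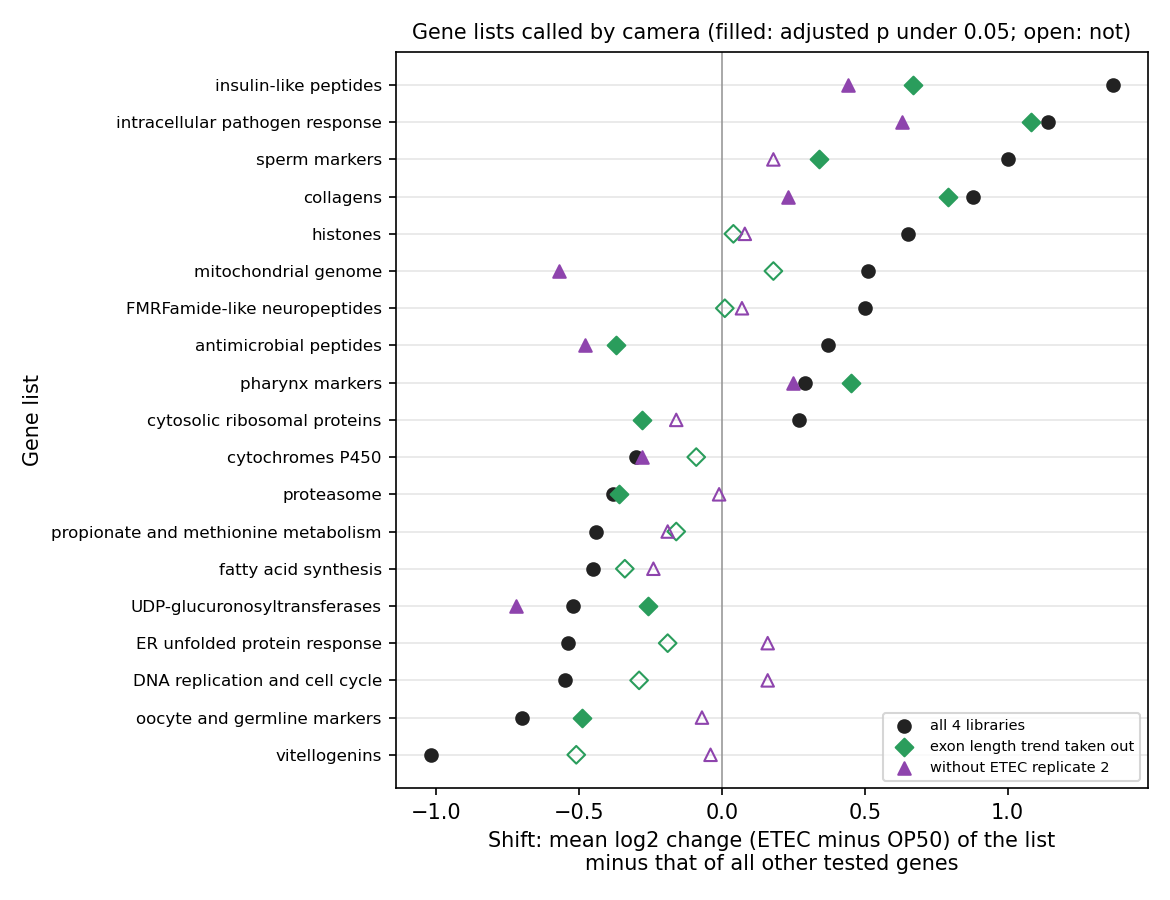
Shift of the 19 called gene lists, the mean log2 change (ETEC minus OP50) of a list minus that of the other tested genes, with all 4 libraries (black circles), with the exon length trend taken out (green diamonds) and without ETEC replicate 2 (purple triangles); filled symbols have a camera adjusted p under 0.05. The intracellular pathogen response stays at 1.14, 1.08 and 0.63, while the antimicrobial peptides go from 0.37 to -0.37 and -0.48.

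Apart from the called lists given above, which include antimicrobial peptides, the intracellular pathogen response and the unfolded protein response of the endoplasmic reticulum, the 10 immune and stress lists that follow and the 11 readout genes fixed beforehand gave no call in the main test. Infection response genes had a list shift of -0.36 (19 tested members, adjusted p = 0.095), lysozymes 0.11 (median log2 change -0.04) and C-type lectins 0.05, with no member called in each. The infection response shift was -0.51 without ETEC replicate 2 (adjusted p = 0.00204), -0.44 with no filter on low counts (adjusted p = 0.0294) and -0.41 with the length trend taken out (adjusted p = 0.034; adjusted p = 0.908 with an estimated correlation). Also with the trend taken out, the lectin genes clec-10 (log2 change 2.50, edgeR adjusted p = 0.0215) and clec-180 (2.46, edgeR adjusted p = 0.00716), named after their values were seen, were called, and neither was without ETEC replicate 2 (adjusted p = 0.438 and 1). Targets of the stress transcription factors DAF-16 and SKN-1 stood at -0.28 and -0.18, cytosolic heat shock genes at 0.05, the mitochondrial unfolded protein response at -0.22, hypoxia and sulfide response at -0.31, glutathione S-transferases at 0.10 and metal handling at 0.08. The DAF-16 shift was -0.77 without ETEC replicate 2 (adjusted p = 3.27e-06), -0.69 without OP50 replicate 2 (adjusted p = 0.00635), 0.05 without OP50 replicate 1 (adjusted p = 0.888) and 0.13 without ETEC replicate 1 (adjusted p = 0.745). It was -0.58 with the length trend taken out (adjusted p = 0.00445; adjusted p = 0.908 with an estimated correlation) and 0.12 with the filter of 5 CPM (adjusted p = 0.648). Over the 11 readout genes, the log2 change ran from -0.82 to 1.15 with an adjusted p of 1 for each. The lysozyme gene lys-7 stood at 2010 and 1410 CPM on OP50 and 1030 and 907 CPM on ETEC (log2 change -0.82, SE 0.76), and clec-60, a lectin gene, at 2.15 and 1.85 CPM against 5.82 and 3.09 CPM (log2 change 1.15, SE 0.73). T24B8.5, a reporter of the p38 kinase PMK-1, stood at 98.6 and 49.2 CPM against 28 and 158 CPM (log2 change 0.33, SE 0.84, and -0.72 with the length trend taken out). For hsp-4, hsp-6, hsp-16.2, gst-4, sod-3, irg-4, irg-5 and vit-2 the log2 changes were -0.36, -0.57, 0.88, -0.69, -0.43, 0.19, -0.42 and -0.36. In simulated counts of this size, a true log2 change of 2 was called in 10.7% of genes with a length trend in 1 library and 15% without. A change of 4 was called in 84.4% and 87.7%. Readout changes of the sizes given above were thus mostly not detectable in such counts with 2 libraries per group.

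The other lists without a call in the main test were embryo markers (shift 0.41, adjusted p = 0.0871), larval molting markers (-0.30), intestine markers (0.01), body wall muscle markers (-0.16), neuron markers (-0.01, median log2 change 0.05), cathepsin-type proteases (-0.22), autophagy and lysosome (-0.16), the respiratory chain and ATP synthase (0.07), receptor guanylate cyclases (0.04) and fatty acid breakdown (-0.03, median log2 change 0.06). In that test no member of them was called over all genes, nor adjusted over the list alone. Receptor guanylate cyclases had a shift of 0.52 with the length trend taken out (adjusted p = 0.0101; adjusted p = 0.908 with an estimated correlation), embryo markers one of 0.38 without ETEC replicate 2 (adjusted p = 0.0471) and 0.74 with the filter of 5 CPM (adjusted p = 0.0131), and cathepsin-type proteases one of -0.50 without OP50 replicate 2 (adjusted p = 0.0288) and -0.41 with no filter on low counts (adjusted p = 0.0334).

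ETEC replicate 2 stood apart from the other 3 libraries. Its correlation with them over tested genes was 0.872 to 0.9, against 0.966 to 0.977 among them. The root mean square log2 difference was 1.27 to 1.44 against 0.63 to 0.77. Counts in this library fell with exon length. Relative to the OP50 mean, the median gene of the shortest-exon quintile (21 to 748 nt) lay 0.90 log2 units higher and that of the longest-exon quintile (2187 to 56341 nt) -1.46, while ETEC replicate 1 gave -0.16 and 0.12. It also had the highest share of ribosomal RNA genes (0.57%, against 0.164% to 0.248%) and of the mitochondrial genome (2.0%, against 0.52% to 0.952%). The 56 called genes had a median exon length of 558.5 nt, against 1297 nt over all tested genes. With the length trend taken out, 165 genes were called, 145 higher and 20 lower, with 52 of the 56 among them.

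**Figure D3:**
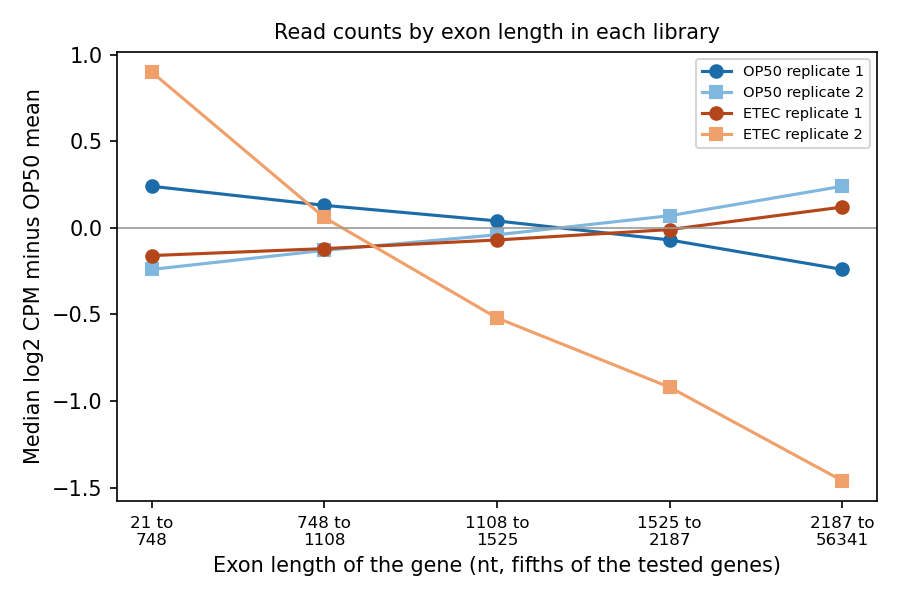
Median log2 CPM minus the mean of the OP50 libraries (vertical axis) for quintiles of tested genes by summed exon length in nt (horizontal axis), among genes with a mean log2 CPM above 4, 1 line per library. The line of ETEC replicate 2 goes from 0.90 to -1.46, and those of the other 3 libraries stay between -0.24 and 0.24.

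Exons of C08E3.1, ceh-5, col-183, bli-1, pals-5 and sod-3 overlap those of a gene on the opposite strand (C08E3.13, ocrl-1, F02D10.10, dph-2, 21ur-13800 and C08A9.3), and the strand setting of the counting is not given in the sources used here, so their counts may include reads of the partner. How reads matching several genes were counted is not given either, which leaves the counts of close paralogs, such as pqn, pals and collagen genes, uncertain.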

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

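The length correction, with preset or estimated correlation, and the crossed block were chosen after the results were seen. Of the 18 called genes that the rule for named genes took, 0 changed sign under the alternatives that tested them, 18 kept the call with the length correction and 13 under each alternative that tested them with all 4 libraries and no block; the filter of 5 CPM tested 8 of the 18, of which 7 kept it throughout. Against 56 genes, 50 higher and 6 lower, the count moved with the filter of 5 CPM (10, 8 and 2; fewer genes tested), limma-voom (34 and 30 higher), the length correction (165, 145 and 20) and, for lower genes, DESeq2 (10); the cause was not tested for the last 3. Leaving out 1 library gave 0 to 2112 genes, 0 to 1527 higher and 0 to 585 lower, with fewer samples. With the replicate number as a block 15 genes were called, 13 higher and 2 lower. The deviations of same-numbered libraries from their group means had a correlation of -0.27, and of -0.01 with the length trend taken out. With 2 libraries per group this cannot exclude a pairing or a shared batch. The labels name no pairing, and the files number the second library of each group otherwise than the titles. With the numbers crossed, 70 genes were called, 14 of them lower. In the list test the block moves nothing, since every gene had the same variance there. Against 19 lists, 11 were called without ETEC replicate 2 and 14 to 15 without each of the others (range 11 to 15), and 0 with an estimated correlation, with fry or with both the length correction and an estimated correlation (0, 1 and 0 at an unadjusted p under 0.05); the cause was not tested. The filter of 5 CPM called 14 lists and ended 6 of the 19 calls, and no filter called 18 and ended 3; the shift of histones was 0.36 with no filter and that of ribosomal proteins 0.44 with the filter of 5 CPM, both called. Upper-quartile factors moved the log2 changes of the genes by a median of 0.29, the filter of 5 CPM by 0.15 and the length correction by 0.16. List shifts are relative to the mean of the other tested genes. The length correction turned the shift of antimicrobial peptides (to -0.37), ribosomal proteins (-0.28), lysozymes (-0.18), glutathione S-transferases (-0.23), heat shock (-0.05), metal handling (-0.04), fatty acid breakdown (0.23), respiratory chain (-0.13), autophagy (0.03), neurons (0.20) and larval molting (0.02), the same with an estimated correlation; of these, antimicrobial peptides and ribosomal proteins were called in the opposite direction (adjusted p = 0.00292 and 0.0118), and 4 lists gained a call. No filter turned C-type lectins (-0.04), heat shock (-0.03), respiratory chain (-0.01), guanylate cyclases (-0.02) and intestine (-0.07), and the filter of 5 CPM turned DAF-16 targets (0.12), heat shock (-0.13), fatty acid breakdown (0.15), autophagy (0.02), muscle (0.02) and neurons (0.11). Leaving out each library, shifts that changed sign ran from -0.48 to 1.32 (antimicrobial peptides), -0.57 to 1.52 (mitochondrial genome), -0.20 to 0.64 (ribosomal proteins), -1.33 to 0.16 (DNA replication), -1.31 to 0.16 (endoplasmic reticulum response), -0.77 to 0.13 (DAF-16 targets), -0.21 to 0.37 (lysozymes), -0.13 to 0.17 (C-type lectins), -0.24 to 0.37 (glutathione S-transferases), -0.05 to 0.07 (heat shock), -0.08 to 0.41 (metal handling), -0.30 to 0.16 (fatty acid breakdown), -0.30 to 0.36 (respiratory chain), -0.55 to 0.15 (autophagy), -0.46 to 0.33 (guanylate cyclases), -0.27 to 0.20 (intestine), -0.43 to 0.03 (muscle) and -0.31 to 0.13 (neurons). Of these, the antimicrobial and mitochondrial lists were called on both sides of 0. Readout genes that changed sign, none called, were T24B8.5 (-0.07 with limma-voom, -0.06 with either block, -0.72 with the length correction, -1.40 to 1.16 leaving out libraries), hsp-4 (0.01 with the length correction; -1.02 to 0.11), hsp-16.2 (-0.20 to 1.58), irg-4 (-0.55 to 2.01) and vit-2 (-1.92 to 0.38). Of the 50 genes called higher, 40 had an ETEC mean under 10 CPM and 9 had 3 or fewer counts over both OP50 libraries, so depth limits how well the size of their changes is known.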

Other observations

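The length correction and every test weighed below were chosen after the results were seen, as were the Gene Ontology, position and neighbour counts. Targets of DAF-16, the transcription factor that insulin signalling restrains, had no call with all 4 libraries (shift -0.28, adjusted p = 0.269). With the length trend taken out their shift was -0.58 (16 tested members, adjusted p = 0.00445; adjusted p = 0.908 with an estimated correlation), with -0.70 and -0.47 in the ETEC libraries and 0.26 and -0.26 in the OP50 libraries. Uncorrected, it was -0.77 without ETEC replicate 2 (adjusted p = 3.27e-06) and -0.69 without OP50 replicate 2 (adjusted p = 0.00635), but 0.13 without ETEC replicate 1 (adjusted p = 0.745) and 0.05 without OP50 replicate 1 (adjusted p = 0.888), so it hung on single libraries of both groups. Infection response genes had shifts of -0.41 (adjusted p = 0.034; adjusted p = 0.908 with an estimated correlation) with the trend taken out and -0.51 (adjusted p = 0.00204) without ETEC replicate 2. Among the DAF-16 targets scl-20 stood at 3.88 and 2.24 CPM on OP50 and 0.0832 and 1.19 CPM on ETEC (length-corrected log2 change -2.75, SE 0.69, edgeR adjusted p = 0.0117, and 0.35 uncorrected). The correction also gave calls to receptor guanylate cyclases (shift 0.52, camera adjusted p = 0.0101) and hypodermis markers (0.49, camera adjusted p = 0.0366), both with adjusted p = 0.908 with an estimated correlation. Neither had a call without ETEC replicate 2 (shifts 0.22 and 0.22). The hypodermis list holds bli-1, with a length-corrected log2 change of 6.45, and its uncorrected median log2 change was 0.01.

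With the length trend taken out, 18 collagens were called higher and 1 lower. Of the 18, 4 were called uncorrected and 2 without ETEC replicate 2. Of 85 annotated genes called higher in that fit, 19 carried the term structural constituent of cuticle, where 1.23 would be drawn by chance (150 of 10342 annotated tested genes, adjusted p = 1.46e-14 over 2115 terms). Uncorrected, 4 of 26 annotated genes called higher carried it, which did not pass (adjusted p = 0.262). The hypergeometric test of terms takes genes as independent draws, also where they vary together, and its p-values do not measure the spread between libraries. The term hormone activity passed in both fits, with ins-3, ins-8, ins-19 and ins-20 among 21 annotated tested genes (adjusted p = 0.000386 uncorrected and 0.0161 with the trend taken out). Without ETEC replicate 2, ins-8 was called and the other 3 were not (log2 changes 1.41, 2.32 and 2.02 for ins-3, ins-19 and ins-20, adjusted p = 1 for each). The gene col-129 stood at 48 and 23.1 CPM on OP50 and 112 and 273 CPM on ETEC (length-corrected log2 change 2.54, SE 0.62, edgeR adjusted p = 0.00815), with an adjusted p of 0.354 uncorrected and a log2 change of 1.65 (adjusted p = 1) without ETEC replicate 2. Chromosome V held 24 of the 56 called genes and 2842 of the 14594 tested, against a median of 13 and a highest of 26 in 10000 random sets matched on expression and length (one-sided permutation test over genes, p = 7e-04). With the length trend taken out it held 50 of 165, against a median of 36 and a highest of 58 (the same permutation test, p = 0.006). Within 10 kb of each other lay 6 pairs of called genes, against a median of 0 and a highest of 5 (the same permutation test, p = 1e-04, the smallest these sets can give), and 19 pairs with the trend taken out, against a median of 4 and a highest of 14 (permutation p = 1e-04). The 6 pairs among the 56 genes all lay on chromosome V, so the chromosome and neighbour counts share genes and are not separate results. The random sets drew genes singly, so neighbours that move together count as separate genes. Of these 6 pairs, trx-5 and oac-32 went in opposite directions (log2 changes 3.97 and -4.64), and the others, such as F09C6.11 and F09C6.13, rose together. How reads matching several genes were counted is not given in the sources used here, which leaves similar neighbours uncertain.

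ETEC replicate 2 stood apart from the other 3 libraries. Its total of 23907896 counts lay within their range, which argues against depth. The length trend as the whole cause is argued against by the difference left after its removal, at least 1.03 log2 units (root mean square) from any other library, where the others differed by at most 0.7. Fewer oocytes and germ cells cannot be told apart from other causes: length-corrected, the oocyte and germline list stood at -0.87 in this library and 5 somatic lists at 0.02 to 0.78, and the range of their differences from another library was 0.49 to 1.04, against 0.82 between the OP50 libraries. RNA breakdown, a different stage and a stronger response to ETEC may each play a part, and were not tested.

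For the genes called higher on ETEC, 46 of the 50 were still called higher with the length trend taken out. The trend was fitted over genes with a mean log2 CPM above 2, and the raised genes had medians of 0.289 CPM on OP50 and 5.81 CPM on ETEC. The kept calls argue against the trend as the whole cause only if weakly expressed genes follow the same trend, which was not tested. Larvae among the collected worms may contribute cuticle collagen transcripts and cannot be told apart from a response of the adults: the length-corrected shift of the larval molting list was 0.02, but its 19 tested members had a median of 12.1 CPM on OP50, which would hide a small share of larvae, and 2 of them had at most 1 CPM there. More embryos cannot be told apart either, since the embryo list had a length-corrected shift of 0.4 (adjusted p = 0.0606) and uncorrected shifts of 0.38 without ETEC replicate 2 (adjusted p = 0.0471) and 0.74 with a filter of 5 CPM (adjusted p = 0.0131). A response to ETEC itself stays open, as the design gives it. Over 14594 genes, ETEC replicate 1 minus OP50 replicate 1 correlated at -0.17 with ETEC replicate 2 minus OP50 replicate 2. With the OP50 libraries exchanged the correlation was 0.13, and with the length trend taken out the 2 values were 0.04 and 0.06. The ETEC libraries thus shared little change over all genes, which does not settle the question for the few called genes.

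Of the 19 gene lists called, 9 were not called in either direction once the length trend was taken out, which is consistent with the trend as a source of their shifts, in full for histones (0.65 to 0.04) and neuropeptides (0.50 to 0.01) but less so for fatty acid synthesis (-0.45 to -0.34, adjusted p = 0.0576). The other 2 that lost their direction, ribosomal proteins (-0.28, adjusted p = 0.0118) and antimicrobial peptides (-0.37, adjusted p = 0.00292), were called lower, and a fall that the trend had covered cannot be told apart from a correction that took out too much. The remaining 8 kept their call and direction, which argues against the trend as their whole cause, provided that weakly expressed members follow the fitted trend. The margin was narrow for UDP-glucuronosyltransferases (-0.52 to -0.26, camera adjusted p = 0.049, and 0.22 in ETEC replicate 2). The shift of sperm markers went from 1 to 0.34 (camera adjusted p = 0.0101). Among these 8, sperm, oocyte and germline markers and the proteasome had no call without ETEC replicate 2 (shifts 0.18, -0.07 and -0.01). The intracellular pathogen response, collagens, insulin-like peptides, pharynx markers and UDP-glucuronosyltransferases were called there as well (shifts 0.63, 0.23, 0.44, 0.25 and -0.72). With all 4 libraries none of them was called with an estimated correlation. Against the OP50 mean, the collagen shift in ETEC replicate 1 (0.22) lay within those of the OP50 libraries (0.33 and -0.33). The pharynx shift (0.27) lay just above OP50 replicate 2 (0.21) and the insulin shift (0.55) above OP50 replicate 1 (0.32). The other lists lay further outside (0.63 against 0.19 in OP50 replicate 2, and -0.72 against -0.17 in OP50 replicate 1). Spread between libraries, a response to ETEC or a difference in stage may lie behind these lists.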
